A study of Mus musculus with 3 samples.

How the data were processed

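Dendritic cells of wild-type C57BL/6 mice were differentiated in vitro with FLT3L, the growth factor that drives dendritic cell development, and were measured by droplet single-cell RNA sequencing (10x Genomics, 3' chemistry). There were 3 libraries, 1 per group: 2 mM glutamine (control), 50 µM glutamine, and 2 mM glutamine with 1 µM DON. DON (6-diazo-5-oxo-L-norleucine) is a glutamine analogue that blocks enzymes that use glutamine.

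The deposited matrices hold raw UMI counts per gene and cell barcode, with barcodes already called as cells by the authors and with no normalisation. The file headers name Cell Ranger 6.0.0, whereas the submitters' processing notes name Cell Ranger 3.1.0 with the mm10 genome, so the version that made the matrices is not settled. The gene annotation is not stated in the sources used here. Of the 32285 genes in the matrices, 99.8% have an identifier that is also in GENCODE vM21 (GRCm38), from which the gene positions were taken.

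Barcodes were kept with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs. Doublets were marked in each library by the Scrublet method, written out here with simulated doublets at 2 per cell and an expected rate of 0.08, and were removed. The threshold was the minimum between the modes of the simulated scores. The marked share was 8.20% in control, 3.92% at 50 µM glutamine and 4.95% with DON. The thresholds differed, at 0.201, 0.294 and 0.251 in that order, and 62.7%, 42.5% and 48.5% of the simulated doublets lay above them. By this measure doublets were detected least completely at 50 µM. This left 9517, 9271 and 8447 cells. Counts were scaled to 10000 per cell and logged. From 2000 variable genes, 30 principal components were computed, and a Jaccard graph of 20 nearest neighbours was clustered once over all 3 libraries by the Leiden method at resolution 1.0, with seed 1 throughout. This gave 24 clusters.

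A cluster was named after a cell type, with the ending -like, when at least 3 markers of a fixed list were 2-fold higher than in the other cells (log2 of at least 1, pseudocount 10 CPM), at least 1 of them was among its 10 highest genes, and no other type had more there. Marker lists of 13 cell types, 31 gene lists and the rules for naming genes were fixed before the data were examined, as were 18 alternatives. Of the 717 genes in the gene lists, 4 had symbols that are not in the matrices, so they were not measured under those symbols. The naming rule gave 2 clusters of cDC1-like cells (type 1 conventional dendritic cells) and 3 of cDC2-like cells (type 2).

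UMIs were summed over the cells of a class in each library and scaled to the class total as CPM. Ratios are log2 of treated over control CPM with 5 CPM added to each. Genes were counted as 2-fold apart among those of at least 20 CPM in at least 1 of the compared libraries. Members of a gene list were measured when they reached 5 CPM in at least 1 library, and members at least 1.5 times higher or lower were counted. Each list median is given with its percentile among 10000 random lists of the same size matched on expression in 20 bins, as a description. With 1 library per group no test between groups is possible, so no p-value, standard error or number of tested genes is given. Intervals are 95% intervals, exact Poisson for CPM and exact binomial (Clopper-Pearson) for shares. They cover counting error only, not variation between cultures or mice. Where a share is 0, the limit given is that of 3 counts. Shares of cells with a UMI of a gene were taken after thinning each cell to 2000 UMIs.

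The named genes are, per treatment and class, the 6 highest and the 6 lowest ratios among genes of at least 50 CPM, without mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and predicted genes. Added to these are up to 4 members of each list with the largest ratios, and a fixed set of 12 genes that includes Xcr1, Clec9a, Batf3, Irf8, Cadm1, Sirpa and Asns. One gene that the rule selects is not reported here. The same rule was applied to the plasmacytoid (pDC-like) and progenitor-like classes. The other classes were left out of the gene comparisons because the study's title concerns conventional dendritic cells.

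List medians are given where the list was far from the random lists (percentile at most 2.5 or at least 97.5) and its median was at least 0.2 in size, or 0.5 in pDC-like and progenitor-like cells. Lists of cDC1 genes, cDC2 genes, ATF4 targets and glutamine genes are given in both cDC classes in any case. The size limits were chosen after the data were seen, because medians near 0 changed sign between settings, and the alternatives were recomputed for the lists given. In the cDC classes, among the medians not given, 51 of 77 changed sign under at least 1 alternative, against 10 of 47 among those given. Single members of the cell cycle and pyrimidine lists in pDC-like and progenitor-like cells were left out of the alternatives, also after their values were seen, unless they were among the 6 highest or lowest genes.

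The alternatives were other cell filters, doublets kept, other resolutions and numbers of variable genes, clustering without cell cycle and response genes, each library clustered on its own, classes given per cell, scaling by median of ratios, CPM without mitochondrial and ribosomal protein genes, cells weighted equally, pseudocounts of 1 and 20 CPM, other CPM limits, cells with few cell cycle UMIs (at most 0.5%), and shares of cells with a UMI without thinning. Another 3 were added after the data were seen: clustering without 75 genes (the cDC1 and cDC2 lists and genes 2-fold apart), clusters weighted as in control, and each cluster of a class alone.

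The size rule was tested on simulated counts in which the treated library had known folds. In cDC1-like cells at the depth of 50 µM glutamine, of 5127 genes run, 98.0% of those set 3-fold apart and 100% of those set 4-fold apart passed the 2-fold rule, and 0% of those set 1.25-fold or 1.5-fold apart. At the depth of DON, also with 5127 genes, these were 98.0%, 98.0% and 0%. In cDC2-like cells, with 5250 genes run, they were 98.0%, 98.0% and 0% for 50 µM glutamine and 100%, 100% and 0% for DON. Of the 4927 unchanged genes in each cDC1-like run and the 5050 in each cDC2-like run, 0 passed. The simulation holds counting error only.

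Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scikit-image 0.26.0, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.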

Results

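Mouse dendritic cells grown with FLT3L were profiled by single-cell RNA sequencing in 3 libraries, with 1 library in each group: 2 mM glutamine, 50 µM glutamine, and 2 mM glutamine with the glutamine antagonist DON at 1 µM. Such cultures hold type 1 conventional dendritic cells (cDC1), which take up dead cells and present their antigens to CD8 T cells, type 2 cells (cDC2), which mainly prime CD4 T cells, plasmacytoid cells (pDC) and their precursors. The control library had 89340379 UMIs in 10497 barcodes, the 50 µM library 92002827 in 9817 and the DON library 87611658 in 8962. The cells used had a median of 6642, 7655 and 7933 UMIs, in that order. None of the differences below could be tested, because no group had a replicate.

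The first question was whether the share of cDC1 depended on glutamine, which the study's title raises. Cells of the cDC1-like class made up 16.3% of the control library (1552 of 9517 cells, 95% interval 15.6 to 17.1%). At 50 µM glutamine they made up 3.37% (312 of 9271, 3.01 to 3.75%), and with DON 9.01% (761 of 8447, 8.41 to 9.64%). Both shares were lower than in control by more than counting error, and at clustering resolution 0.6 the 50 µM share was 6.64%. The cDC2-like class was 24.5% in control (23.6 to 25.4%), lower at 50 µM with 17.3% (16.5 to 18.1%), and near control with DON at 23.4% (22.5 to 24.3%). Among cDC1-like and cDC2-like cells together, the cDC1-like part was 40.0% (38.4 to 41.5%) in control, 16.3% (14.7 to 18.0%) at 50 µM and 27.8% (26.1 to 29.5%) with DON. At resolution 0.6 these were 39.7%, 26.4% (24.6 to 28.2%) and 29.2% (27.7 to 30.8%), so that the treatments lay close together there.

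Other classes differed as well. Progenitor-like cells were 4.28% of control cells, 17.8% at 50 µM and 5.67% with DON. Mature DC-like cells, which carry Ccr7 and Fscn1, were 4.70%, 2.33% and 2.70%. The pDC-like class was 27.9%, 23.6% and 28.9%. Monocyte or macrophage-like cells were 3.56%, 4.24% and 4.65%, neutrophil-like cells 2.87%, 3.84% and 3.74%, and B lineage-like cells 1.18%, 2.57% and 1.54%. Unnamed clusters held 12.9%, 23.2% and 18.8%. The 3 largest of these, in which no class had a marker among the 10 highest genes, had cell cycle genes such as Mcm3, Nusap1 and Cdc20 there.

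**Figure D1:**
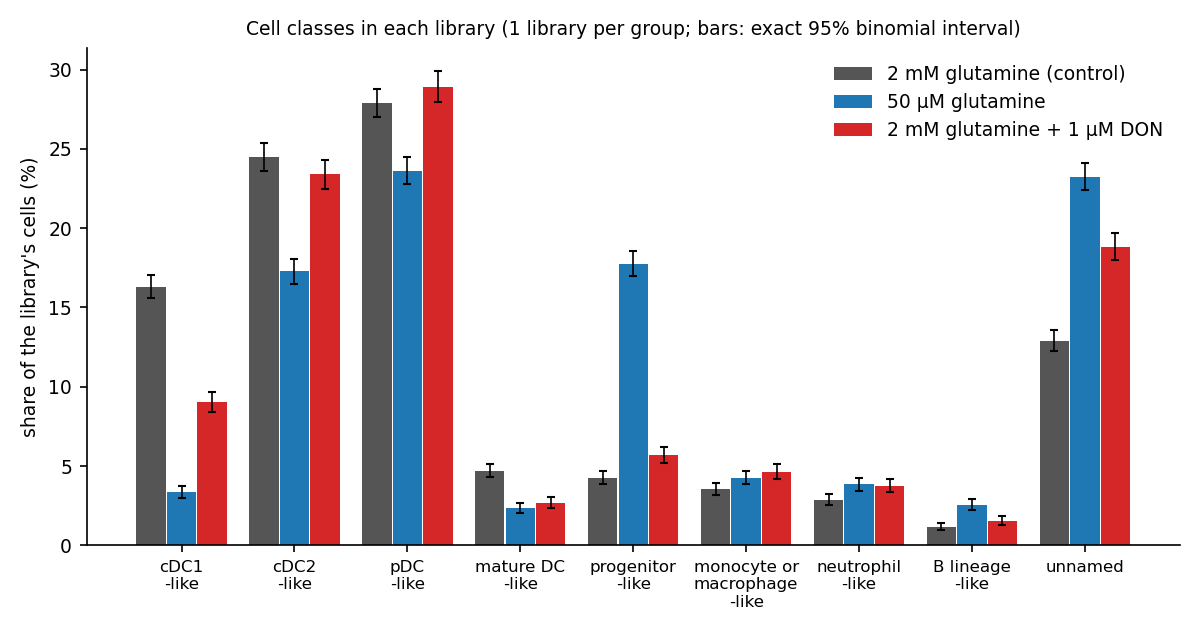
Share of each library's cells (percent) in each cell class, with 1 bar per library and exact 95% binomial intervals. The cDC1-like bar stands at 16.3% in control, 3.37% at 50 µM glutamine and 9.01% with DON, and the progenitor-like bar at 4.28%, 17.8% and 5.67%.

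The comparison of 50 µM glutamine with control in cDC1-like cells asked how the mRNA of the class differed. The class had lower mRNA of glycolytic genes and a lower median of cholesterol synthesis genes. Most cDC1 identity genes were near their control level, but Xcr1 was lower, and several genes typical of cDC2 had higher values. For the latter, admixture of cDC2-like cells was not excluded. Of 5579 genes compared, 18 were at least 2-fold higher and 17 at least 2-fold lower. These counts depended on the clustering, with 105 higher and 35 lower at resolution 0.6, and 20 higher and 108 lower when each library was clustered on its own. The class had 2959344 UMIs at 50 µM and 16406119 in control, so that the treated values carry the wider intervals.

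Among identity genes, Xcr1, the receptor for the chemokine XCL1 and the usual mark of cDC1 (ENSMUSG00000060509, chromosome 9, 123852315 to 123862029 of GRCm38), had 132 CPM in control (127 to 138) and 72.7 CPM at 50 µM (63.3 to 83.0), a log2 ratio of -0.82. That ratio depended on the clustering and was -1.65 at resolution 0.6, as low as with DON, and -0.59 with each library clustered on its own. After thinning, 17.7% of control cDC1-like cells (15.8 to 19.7%) and 10.9% of those at 50 µM (7.67 to 14.9%) had an Xcr1 UMI, against 0.113% and 0.137% of pDC-like cells, which should lack it. Median depths before thinning were 9255 and 8579 UMIs in the cDC1-like class, and 5329 and 5822 in the pDC-like class. Clec9a, the receptor for dead cells (ENSMUSG00000046080, chromosome 6, 129408862 to 129424763), was at 70.6 and 73.7 CPM, and Irf8, the factor that cDC1 and pDC need, at a log2 ratio of -0.09. Batf3, the factor that keeps Irf8 on in cDC1, was lower (161 and 112 CPM, -0.50), as was Cd24a (-1.19), whereas Cadm1 was at 0.35. The 20 measured cDC1 genes had a median of -0.14 (percentile 0.130), with 4 at least 1.5 times lower and 0 higher, and that median was 0.06 when each library was clustered on its own.

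The cDC2 genes had a median of 0.56 in the same cells (percentile 100), with 5 of 14 at least 1.5 times higher. Mixing in of cDC2-like cells would need shares with a median of 7.92% for the 13 cDC2 genes other than Cd209a that could be assessed. These shares ran from -2.23% for Clec10a to 17.6% for Clec4b1, so no single share gives all the levels. S100a4, Itgam and Tnip3, which were higher, needed 9.58%, 11.8% and 16.2%, against 1.44% for Cd7. Admixture was not told apart from expression, so the list is not read as expression by cDC1-like cells. Cd209a, a C-type lectin of cDC2 (ENSMUSG00000031494, chromosome 8, 3743397 to 3748984), was highest of all named genes, with 11.9 CPM in control (10.3 to 13.7) and 106 CPM at 50 µM (94.4 to 118), a log2 ratio of 2.71. Itgam (1.20), Tnip3 (1.17) and S100a4 (0.91) were higher too. The remaining highest genes of at least 50 CPM were Tmem176b (1.52) and Tmem176a (1.46), which encode ion channels of the antigen presentation pathway, the integrin Itga1 (82.0 and 226 CPM, 1.41), Tnfaip2 (1.33) and the prostaglandin-degrading enzyme Hpgd (1.19). Hpgd is also among the 10 highest genes of a cDC2-like cluster. NF-kB and inflammatory genes had a median of 0.39 with Nfkb2 at 0.81 and Nfkbia at 0.77, while Ccl5 of the same list was among the lowest genes (74.2 and 11.2 CPM, -2.29). Ccl5 is the highest gene of mature DC-like cells (15849 CPM in control) and was lower in pDC-like cells too (27.8 and 10.2 CPM). It was nearer to control in cDC2-like cells (35.94 and 30.04 CPM) and progenitor-like cells (22.38 and 20.57 CPM). The drop was thus not alike in all classes, and stray RNA was not told apart from a difference within cDC1-like cells. The ratio in cDC1-like cells was -0.92 with doublets kept. Since its size depended on doublet removal, Ccl5 is not read as a difference of cDC1-like cells. These levels in other classes were looked up after the ratio had been seen. Maturation genes had a median of 0.29, with Marcksl1 at 0.96 and Relb at 0.87 but Ccr7 lower (8.35 and 1.69 CPM). In cluster 13 of the class alone that median was -0.18. This cluster is the cycling part of the class, with 1.69% of UMIs from the cell cycle lists against 0.302% in cluster 3.

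Glycolysis genes had a median of -0.66 (percentile 0), with 10 of 18 at least 1.5 times lower. Pgk1 was at 537 and 171 CPM (-1.62) and Aldoa at 698 and 247 CPM (-1.48), and the lactate exporter Slc16a3 was lower as well (-1.72). The lowest gene was Ankrd37, a target of the hypoxia factor HIF1 (ENSMUSG00000050914, chromosome 8, 45996902 to 46005707), at 56.8 CPM in control (53.2 to 60.6) and 4.39 CPM at 50 µM (2.34 to 7.51), a log2 ratio of -2.72. Mif (740 and 210 CPM, -1.79) and Aldoc (-1.77) were the next outside chemokines. Cholesterol synthesis genes had a median of -0.41 (percentile 0), with 4 of 23 at least 1.5 times lower, Fdps at 331 and 181 CPM (-0.85) and Msmo1 at -0.70. Genes of S phase had a median of 0.31, which was -0.07 with each library clustered on its own. The targets of ATF4, the factor that cells switch on when amino acids run short, had a median of 0.20 (percentile 96.9), with 5 of 31 at least 1.5 times higher. Asns, which uses glutamine to make asparagine, was at 3.54 CPM (2.68 to 4.57) and 17.2 CPM (12.8 to 22.7), a log2 ratio of 1.38, and the transporter Slc7a5 at 1.01. Genes of glutamine uptake and use had a median of 0.10.

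With DON, cDC1-like cells had lower mRNA of their own identity genes and lower medians of maturation and inflammatory genes. The medians of cell division and sterol synthesis genes were above control, although few single members reached 1.5-fold. Of 5429 genes compared, 0 were at least 2-fold higher and 10 were at least 2-fold lower, among them Cd81 (37.1 CPM in control, -1.92), which lies below the 50 CPM of the naming rule and was picked after its value was seen. The cDC1 genes had a median of -0.61 (percentile 0), with 10 of 20 at least 1.5 times lower. Xcr1 was at 38.7 CPM (34.8 to 43.0), a log2 ratio of -1.65, and 6.84% of thinned cells (5.15 to 8.88%) had an Xcr1 UMI, against 0 of 2438 pDC-like cells, which allows a share of up to 0.123%. Median depths there were 10681 and 6453 UMIs. Cadm1, an adhesion molecule of cDC1, fell short of control as well (44.9 and 18.2 CPM, -1.11), with Plpp1 (-1.10) and Itgae (-1.10), the latter encoding CD103. Clec9a was lower (48.1 CPM, -0.51), whereas Irf8 (-0.02) and Batf3 (-0.07) were near control. The thinned shares of cells with a Clec9a UMI had overlapping intervals, 11.8% in control (10.3 to 13.5%) and 10.7% with DON (8.55 to 13.1%).

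Ccl5, a chemokine that draws T cells, was lowest among genes of at least 50 CPM with DON (6.92 CPM, -2.73), but it was lower in pDC-like cells as well (27.8 and 8.46 CPM), and mature DC-like cells, its main source, were 4.70% of control cells and 2.70% with DON. It was followed by Ctla2b (153 and 39.6 CPM, -1.82), Xcr1, Ankrd37 (19.6 CPM, -1.33), Tgfbi (-1.01) and Rtl8a (-0.93). Medians were -0.35 for maturation genes (3 of 12 at least 1.5 times lower, Ccr7 -0.93, Cd83 -0.67), -0.21 for NF-kB and inflammatory genes (2 of 14, Ier3 -0.94), -0.24 for immediate early genes (Atf3 -1.11, Egr1 -1.06) and -0.23 for type I interferon genes. Ccr7 and other maturation genes are also markers of the mature DC-like class, and stray RNA or cells of that class were not told apart from a difference within cDC1-like cells. Glycolysis genes had a median of -0.29 (percentile 0), with Slc16a3 at -1.44 and Pgk1 at -0.57. Cholesterol synthesis genes, at 0.41 (percentile 100), lay on the other side of control from their value at 50 µM, with Hmgcs1 at 117 and 173 CPM (0.55), and 1 of 23, Hsd17b7 (0.68), at least 1.5 times higher. Fatty acid synthesis genes had a median of 0.28, with Fads2 at 0.49.

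The highest genes of at least 50 CPM with DON were S100a4 (259 and 424 CPM, 0.70), the S phase gene Cdca7 (0.63), the heterochromatin protein gene Cbx5 (0.63), Fam111a (0.63), Ms4a4c (0.62) and Gcnt2 (0.60). Medians of 0.35 for S phase (2 of 41 at least 1.5 times higher, Cdca7 and Prim1), 0.33 for G2 and M phase (0 of 49), 0.24 for MYC and ribosome genes, 0.25 for pyrimidine synthesis and 0.21 for purine synthesis went with this. The cycling cluster 13 held 35.7% of the class with DON and 27.0% in control, so these medians include the mix of cells. The cDC2 genes were at 0.21, much below their value at 50 µM. S100a4 is one of them, and Ms4a4c is among the 10 highest genes of cDC2-like cluster 1. Admixture of cDC2-like cells was not told apart from expression with DON either. Medians for ATF4 targets (0.12, percentile 88.7) and glutamine genes (0.09) were within the range of random lists. Their largest member, Slc7a5, was at 9.57 and 20.8 CPM (0.82), while Asns (0.15) lay within counting error of control.

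**Figure D2:**
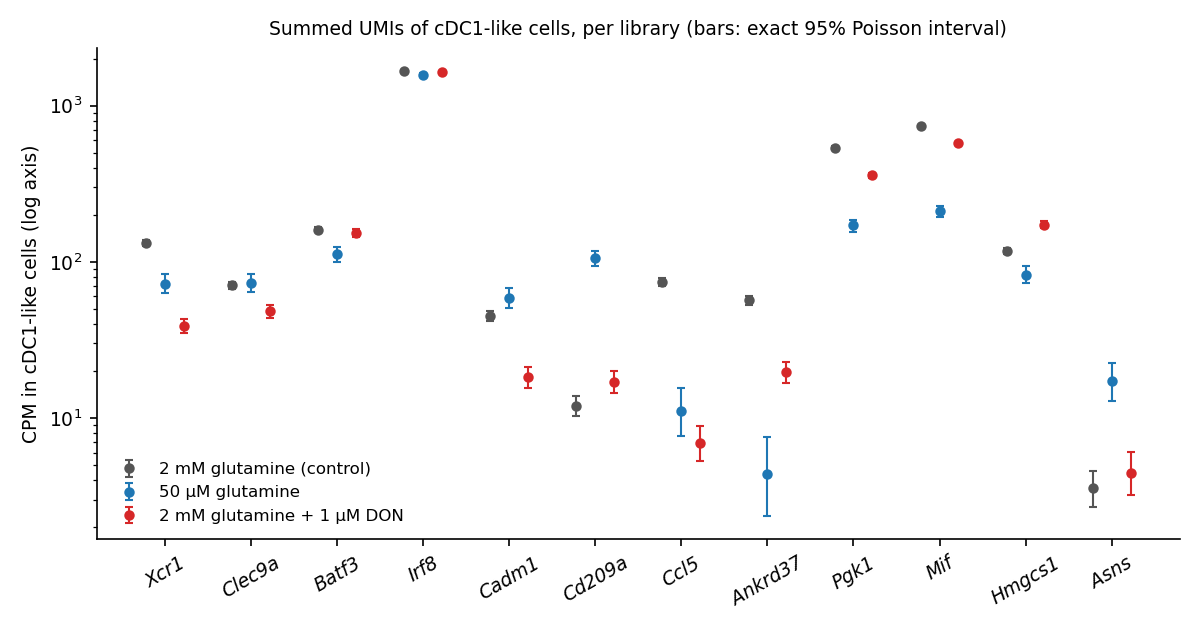
CPM of 12 genes in cDC1-like cells (log axis), 1 point per library, with exact 95% Poisson intervals. Xcr1 stands at 132 CPM in control, 72.7 at 50 µM glutamine and 38.7 with DON, and Cd209a at 11.9, 106 and 17.0.

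In cDC2-like cells the question was which of these differences were shared by the class whose share was nearer to control. At 50 µM glutamine, glycolysis and cholesterol genes had medians below control as in cDC1-like cells, as had MHC class II genes, and oxidative stress, inflammatory and maturation genes had medians above it. Of 5733 genes compared, 15 were at least 2-fold higher and 21 at least 2-fold lower, against 53 and 38 with each library clustered on its own and 44 and 26 with classes given per cell. The class was made of 3 clusters in different proportions: cluster 1, with Cd209a and Clec4b1 among its highest genes, held 46.4% of the class in control and 38.2% at 50 µM, cluster 2, with Ltb and S100a4, held 30.2% and 49.8%, and cluster 9, with Cd7 and Klf4, held 23.4% and 12.0%.

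Glycolysis genes had a median of -0.60 (percentile 0), with 9 of 18 at least 1.5 times lower, among them Pgk1 (396 and 127 CPM, -1.61), Slc16a3 (-1.37) and the glucose transporter Slc2a1 (-1.04). Ankrd37 was again the lowest gene (95.4 and 4.59 CPM, -3.39), before Aldoc (-2.32), Mif (-1.86), Pgk1, the fatty acid desaturase Scd2 (-1.36) and Ifi30 (-1.24). Cholesterol synthesis genes had a median of -0.29, with 2 of 23 at least 1.5 times lower and Fdps at -0.84. The MHC class II list had a median of -0.39 (percentile 0), with 3 of 14 at least 1.5 times lower: Ifi30, a reductase that unfolds antigens, and the peptide-loading genes H2-Ob (-0.82) and H2-DMb2 (-0.72).

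Lyz2, which is also abundant in macrophages and neutrophils, was the highest gene of at least 50 CPM in cDC2-like cells at 50 µM (415 and 1251 CPM, 1.58), followed by Tnfaip2 (1.52), Ltb (1.42), Ly6d (1.32), Fyb (1.13) and Haus8 (1.08). Ly6d is also a pDC marker, and its ratio was -0.47 with doublets kept. Ltb was at -0.10 in cluster 1 alone and -0.45 in cluster 9 alone. Sirpa, the surface mark of cDC2, was at 76.7 and 133 CPM (0.76) and Csf1r at 0.82. Cd80 (0.97), Il4i1 (0.76) and Icam1 (0.59) led the maturation list (median 0.42, 4 of 14 at least 1.5 times higher), and Nfkbia (0.87), Cxcl16 (0.85) and Nfkb2 (0.75) the inflammatory list (0.41, 6 of 15). The NRF2 targets of oxidative stress had a median of 0.52 (percentile 100, 5 of 13), with Txnrd1 at 0.98 and Gsr at 0.96. Smaller medians were 0.34 for chemokine, Toll-like and cytokine receptors, 0.33 for enzymes that use alpha-ketoglutarate (demethylases and HIF prolyl hydroxylases), 0.28 for respiratory genes of the mitochondrial genome, which made up 3.35% of the class's UMIs in control and 3.98% at 50 µM, and 0.24 for G2 and M phase. The cDC2 list had a median of 0.16, which was -0.01 when scaled by median of ratios, and the cDC1 list had -0.10, which was 0.07 with classes given per cell. The ATF4 targets had a median of 0.07, which was -0.07 under that scaling, although Asns was at 2.80 and 10.6 CPM (1.00) and Phgdh, the first enzyme of serine synthesis, at 0.84. Glutamine genes had a median of 0.16.

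With DON, cDC2-like cells were close to control. Of 5479 genes compared, 0 were at least 2-fold higher and 2 were lower, Ankrd37 (95.4 and 41.8 CPM, -1.10) and Slc16a3 (27.5 and 11.2 CPM). Sterol genes had a median of 0.33 (percentile 100), with 1 of 23, Hmgcs1 (80.5 and 127 CPM, 0.63), at least 1.5 times higher and Fdps at 0.48. S phase genes had a median of 0.25. Glycolysis genes had a median of -0.25 (percentile 0), with Tpi1 at -0.74 and Pfkl at -0.72, and MHC class II genes one of -0.28, with H2-DMb2 at -0.78, H2-Ob at -0.67 and H2-Eb1 at -0.60. H2-Eb1 is among the 10 highest genes of cluster 1, whose share of the class was smaller with DON, so its ratio includes the mix of clusters given next. H2-DMb2 is among those of cluster 2, whose share was larger with DON. That shift goes the other way from the lower H2-DMb2. Clec10a (-0.67), Clec4b1 (-0.57) and Cd209a (-0.54), all lectins of cDC2, had ratios below control, but the mix of clusters differed: cluster 1 held 46.4% of the class in control and 32.4% with DON, cluster 2 held 30.2% and 37.6%, and cluster 9 the rest. With clusters weighted as in control the ratios of these lectins were -0.42, -0.28 and -0.23. The cDC2 list as a whole was at -0.12 and changed side in 2 of the 3 clusters alone. The highest genes of at least 50 CPM beside the sterol genes were the neutrophil gene S100a9 (36.1 and 58.9 CPM, 0.64), Pclaf (0.61), the transferrin receptor Tfrc (0.57) and the pDC gene Siglech (0.53). The cDC1 genes (-0.01), ATF4 targets (0.07) and glutamine genes (0.03) had medians near 0, with Asns at -0.06.

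The last question was how far the treatments resembled each other. In cDC1-like cells 3 genes were at least 2-fold lower under both, namely Ankrd37, Ccl5 and Slc16a3, with the same control library in both comparisons and with the limits given above for Ccl5. In cDC2-like cells the genes lower under both were the 2 named for DON. The log2 ratios of the treatments correlated with r = 0.249 across 5310 genes of cDC1-like cells and r = 0.419 across 5426 genes of cDC2-like cells. Sharing 1 control library gives a positive r by counting error alone: simulated unchanged groups had a mean r of 0.232 and 0.438. Those groups vary by counting error only, so their r cannot be set against that of the data. The covariance was 0.0124 against 0.0022 in simulated groups for cDC1-like cells, and 0.0139 against 0.0021 for cDC2-like cells. With control cells split at random, so that each treatment had its own control cells, r was 0.184 and 0.311. The covariance was then 0.0095 and 0.0113, so counting error of the shared control makes up only a small part of it. The control culture itself was still shared. Genes are not independent replicates, and these values describe the 3 libraries alone.

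**Figure D3:**
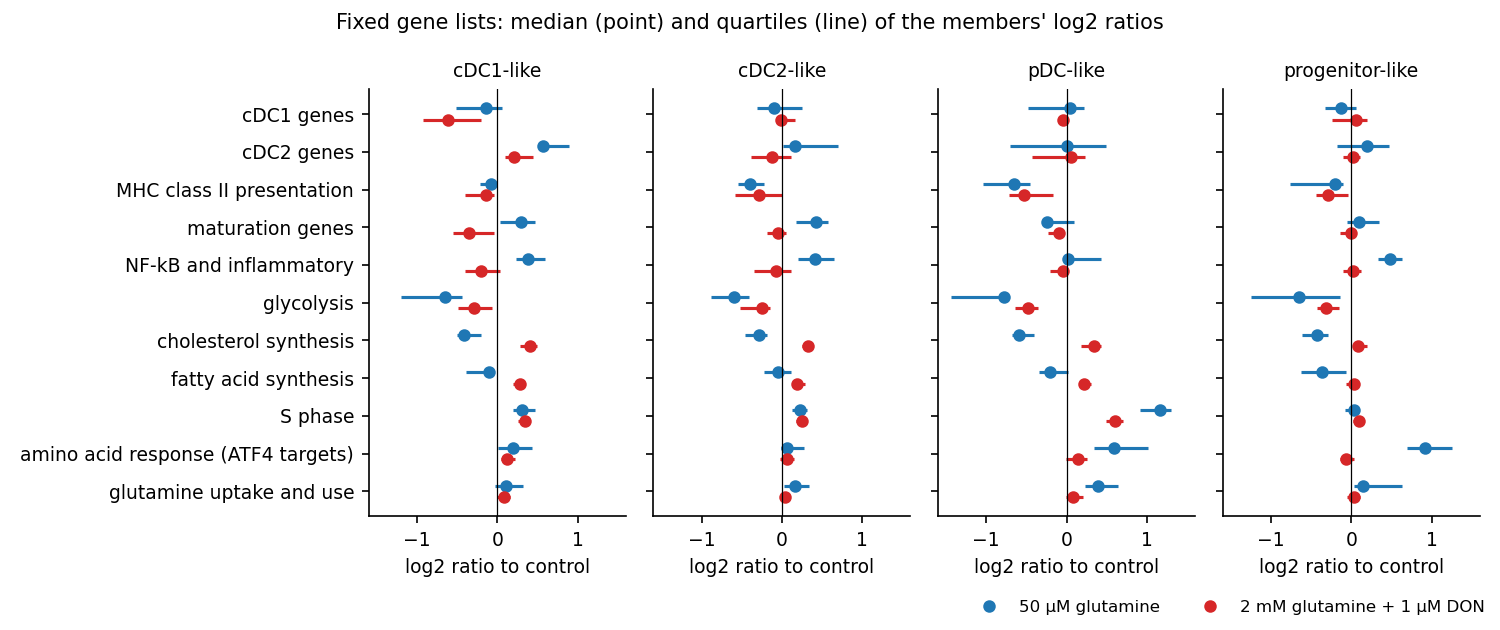
Median log2 ratio to control (point) and quartiles (line) of the measured members of 11 fixed gene lists in 4 cell classes, for 50 µM glutamine and for DON. In cDC1-like cells glycolysis stands at -0.66 and -0.29, cholesterol synthesis at -0.41 and 0.41, and the cDC1 genes at -0.14 and -0.61.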

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

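Of the tests below, those on cell filters, dilution, variation between cultures, free RNA and hypoxia genes were chosen only after the result they address had been seen.

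The lower cDC1-like share under both treatments was the main pattern weighed. Filters and doublet calling are argued against, since the highest DON share over the filter alternatives was 10.4% (9.68 to 11.1%) and the lowest control share 16.1% (15.3 to 16.8%). Cells that kept cDC1-specific transcripts but were named otherwise would have held these transcripts up in the whole library. Genes that kept their level within the class had median whole-library log2 ratios of -1.59 at 50 µM (9 genes) and -0.86 with DON (6 genes). The shares had -2.28 and -0.86, so other naming of such cells could hold at most a part of the difference at 50 µM. Cells that had lost cDC1 transcripts and were therefore named otherwise would give the same values, so the test cannot exclude them. Dilution by other classes would have left the cDC1-like part of cDC1-like and cDC2-like cells together at its control value of 40.0%. That part was 16.3% at 50 µM and 27.8% with DON (26.4% and 29.2% against 39.7% at resolution 0.6). Mature DC-like cells and the unnamed clusters, the largest of them cycling, are not in it. The cDC1-like class includes the cycling cluster 13, with 1.69% of UMIs from the cell cycle lists. The cDC2-like clusters 1, 2 and 9 had 0.182%, 0.381% and 0.196%. How cycling cells are named could thus also move that part, which was not tested. An effect of glutamine supply on the yield or survival of cDC1 is a candidate explanation, but with 1 library per group it cannot be told apart from variation between cultures. It was also not told apart from a loss of cDC1 transcripts by cells still present.

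Lower medians of glycolysis genes under both treatments in cDC1-like, cDC2-like, pDC-like and progenitor-like cells were the next pattern. Scaling is argued against by the highest of the 8 medians under median of ratios, -0.32, and a different share of cycling cells by that among cells with few cell cycle UMIs, -0.26. In progenitor-like cells the latter rests on only 25 cells in control, 96 at 50 µM and 12 with DON. For free RNA, both tests used only the drop at 50 µM. The first, the ratio of the largest to the smallest drop of summed CPM between classes, gave 1.57 and decided nothing. A further test chosen after that put the part of the drop in pDC-like cells that free RNA could hold at 18.5%. This was close under the limit of 20% set for it, which argues against free RNA as the whole cause at 50 µM. For DON neither test was run, and the drop was smaller there. In pDC-like cells the summed CPM of the list was 4454 in control, 2206 at 50 µM and 3364 with DON. Free RNA was therefore not excluded for DON. A weaker hypoxia response stays open. Hypoxia genes outside glycolysis had class medians from -0.28 to -0.17 at 50 µM, and from -0.27 to -0.0653 with DON. Their percentile among random lists was 0 in every class under both treatments, except 0.2 in cDC1-like cells with DON. Between 3 and 5 members per class were at least 1.5 times lower at 50 µM, and 1 or 2 with DON. In cDC1-like cells with DON the median passed the limit of -0.1 set against the explanation. Its quartiles (-0.29 to -0.01) spanned that limit, a condition added after the value was seen. Oxygen and cell density were not used here, so a direct effect of glutamine cannot be told apart from theirs.

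Higher Cd209a in cDC1-like cells at 50 µM was weighed because the gene belongs to cDC2. To reach the level of Cd209a by mixing, 85.1% of the class would have to be cDC2-like cells of that class's average profile. The 13 other cDC2 genes needed a median of 7.92% (from -2.23 to 17.6%). Mixing at the average profile is thus argued against. Cd209a is, however, first among the highest genes of cDC2-like cluster 1, which held 38.2% of its class at 50 µM. Cells of that cluster alone could need a smaller share, which was not computed, so their admixture was not excluded. Free RNA would reach all classes alike, but 1.01% of pDC-like cells (0.632 to 1.52%) and 17.6% of cDC1-like cells (13.6 to 22.3%) had a Cd209a UMI after thinning. Expression of Cd209a by cells of the cDC1-like class may explain this, as a hypothesis found and tested on the same 3 libraries, and variation between cultures was not tested.

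Maturation genes at 50 µM were singled out because their medians went opposite ways in different classes, 0.29 in cDC1-like and 0.42 in cDC2-like cells but -0.24 in pDC-like cells; the difference itself was not tested. Outside the conventional classes, list medians of at least 0.5 in size were singled out as signals in cells that the main comparisons do not use. In pDC-like cells at 50 µM they were 1.27 for G2 and M phase, 1.17 for S phase, 0.72 for pyrimidine synthesis, 0.59 for ATF4 targets, -0.52 for type I interferon genes, -0.60 for cholesterol synthesis, -0.66 for MHC class II and -0.78 for glycolysis. With DON the same class had 0.75 for G2 and M phase, 0.60 for S phase and -0.53 for MHC class II. Progenitor-like cells at 50 µM had 0.92 for ATF4 targets, 0.60 for p53 targets and -0.66 for glycolysis.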

How the results depend on the processing

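The alternatives with single clusters, with clusters weighted as in control and without 75 defining genes were chosen after seeing the data, as were the size limits for the lists given. The cDC1-like share was lower than control under both treatments in all 10 alternatives that redefine cells or classes, and lowest at 50 µM. It was 17.4% in control and 10.2% with DON at 2000 UMIs. With the 5% mitochondrial limit it was 17.8% in control, 3.95% at 50 µM and 10.4% with DON. Resolution 0.6 gave 18.3%, 6.64% and 11.1%, resolution 1.5 gave 17.8%, 4.09% and 11.1%, and 1000 variable genes gave 14.9%, 2.98% and 7.61%. Classes given per cell gave 15.2% in control and 7.90% with DON, and clustering each library on its own 2.66% at 50 µM. The cause of these shifts was not tested.

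Counts of genes at least 2-fold apart moved more. In cDC1-like cells at 50 µM the 35 genes became 140 at resolution 0.6 (105 higher, 35 lower), 128 with each library clustered on its own (20 higher, 108 lower) and 92 in cluster 13 alone; the cause was not tested. With pseudocount 20 they became 16, and with at least 100 CPM 15. For DON in these cells the 10 genes became 18 without mitochondrial and ribosomal genes, 17 with pseudocount 1, 4 with pseudocount 20, 18 without a CPM limit, 2 with at least 100 CPM and 17 among cells with few cell cycle UMIs. In cDC2-like cells at 50 µM the 36 genes became 91 with each library on its own, 70 with classes per cell, 56 with pseudocount 1, 13 with pseudocount 20, 10 with at least 100 CPM and 62 in cluster 9 alone. The 2 genes for DON became 1 in the clusterings without response lists and without defining genes and with classes per cell, 4 without mitochondrial and ribosomal genes and with pseudocount 1, 0 with pseudocount 20 and with at least 100 CPM, and 7 in cluster 9 alone. A larger pseudocount shrinks ratios and a higher CPM limit leaves fewer genes by construction, as 1408 instead of 5579 genes were compared in cDC1-like cells at 50 µM; the cause of the others was not tested. Scaling by median of ratios moved the median of all genes from 0.08 to -0.02 in cDC1-like and from 0.12 to -0.02 in cDC2-like cells at 50 µM, which turned 18 higher and 17 lower genes into 14 and 21, and 15 and 21 into 10 and 30.

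Glycolysis medians kept their sign under the alternatives run, from -0.88 to -0.52 in cDC1-like cells at 50 µM and from -0.37 to -0.23 with DON, and so did Xcr1 in these cells, from -1.65 to -0.59 and from -1.79 to -1.37. Changes of sign among list medians far from the random lists and genes at least 2-fold apart were as follows, and their cause was not tested. With each library on its own, cDC1 genes (0.0605) and S phase (-0.0664) in cDC1-like cells at 50 µM. In cluster 13 alone, maturation genes there (-0.18). In cDC2-like cells at 50 µM, cDC1 genes with classes per cell (0.0662), with weighted clusters (0.0407) and in cluster 1 (0.0006), Haus8 in cluster 9 (-0.0676), Ltb in clusters 1 (-0.10) and 9 (-0.45), and Ly6d with doublets kept (-0.47) and in cluster 9 (-0.16). With DON there, cDC2 genes in clusters 1 (0.0064) and 9 (0.0891). In pDC-like cells at 50 µM, pyrimidine synthesis (-0.13) and G2 and M phase (-0.0378) in cluster 8, Cd74 (0.0298) and H2-Eb1 (0.17) in cluster 6 and Knl1 in cluster 11 (-0.0746). In pDC-like cells with DON, S phase in cluster 8 (-0.0184), Gem (-0.52), Mki67 (-0.20) and Top2a (-0.0068) in cluster 11, and Nusap1 in clusters 0 (-0.0455) and 6 (-0.15). In progenitor-like cells at 50 µM with few cell cycle UMIs (96 cells, and 25 in control), Bbc3 (-0.0553) and Cdkn1a (-0.75). Other list medians given, not far from the random lists, also changed sign. Under median of ratios in cDC2-like cells at 50 µM, ATF4 targets became -0.07 and cDC2 genes -0.0073, and glutamine genes became -0.02 in cDC1-like cells at 50 µM. In cDC2-like cells with DON, glutamine genes were -0.02 under median of ratios and within 0.01 below 0 with 1000 variable genes and in clusters 1 and 9 alone, and cDC1 genes were 0.0267 without response lists and 0.0381 in cluster 2. Smaller ratios of single genes are not listed. Depth limits the 312 cDC1-like cells at 50 µM most, and with it genes of few CPM such as Ankrd37 there.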

Other observations

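In progenitor-like cells, which carry Cd34 and Mpo, 50 µM glutamine went with the amino acid response that was small in conventional dendritic cells: 35 of 43 measured ATF4 targets were at least 1.5 times higher than in control. Asns was at 20.1 and 140 CPM (log2 ratio 2.53), Atf5 at 5.56 and 54.5 CPM (2.49), the amino acid transporter Slc7a5 at 1.92, the mitochondrial enzyme Pck2 at 1.56, and the glutamine transporter Slc1a5 at 0.82. Cluster 4, which has Asns among its highest genes, held 69.5% of the class in control and 66.5% at 50 µM, and the median of the targets was 1.02 in cluster 4 alone, 0.64 in cluster 14 alone and 0.53 among cells with few cell cycle UMIs. The last value rests on 25 control cells and 96 cells at 50 µM. With DON the median of these targets was -0.06 and Asns was at -0.36. Cox6a2, a pDC marker, was the highest gene of the class at 50 µM (88.4 and 668 CPM, 2.85). Ankrd37 (-3.16), Bnip3 (-1.76) and Pgk1 (-1.58) were lowest at 50 µM, and Ankrd37 (-1.50), Bnip3 (-1.23) and H2-Ab1 (-0.86) with DON.

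The pDC-like class held 4 clusters. Cluster 8, with histone and cell cycle genes among its highest, made up 9.12% of the class in control (8.05 to 10.3%), 32.5% at 50 µM (30.5 to 34.5%) and 18.3% with DON (16.8 to 19.9%), and Mki67 was at 137, 498 and 281 CPM over the class. Within cluster 8 alone the G2 and M phase median at 50 µM was -0.04. Asns was at 1.22 and 22.3 CPM (2.14) at 50 µM. Of 14 MHC class II genes, 8 were at least 1.5 times lower at 50 µM and 6 with DON, with H2-Eb1 at -1.10 and -0.89. The mix of clusters differed too: cluster 0 held 57.8%, 32.9% and 43.3% of the class, cluster 6 held 17.3%, 26.9% and 24.4%, and cluster 11 held 15.8%, 7.76% and 14.0%. In cluster 6 alone H2-Eb1 was at 0.17 and Cd74 at 0.03 at 50 µM.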
